A study of Dictyostelium discoideum with 35 samples.

How the data were processed

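RNA sequencing measured transcript levels in Dictyostelium discoideum amebae of the laboratory strain AX3, as wild type (WT) and as a mutant with an insertion in ttpA. The gene ttpA codes for a protein of the tristetraprolin family, whose zinc finger proteins bind AU-rich elements in mRNA and promote mRNA decay. Per the labels' protocols, amebae grew axenically on plastic until nearly confluent and were frozen (0 h), or separate cultures spent 2 h or 6 h in a medium poor in nutrients before harvest. Total RNA was purified on spin columns and made into libraries with an Illumina TruSeq RNA kit, per the labels' protocols. The submitters' processing notes name bcl2fastq, STAR 2.5.2b and featureCounts 1.5.1. The genome build, the annotation and the strand setting of the counting are not given in the sources used here.

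The authors deposited a table of raw read counts per gene, with 12865 genes in rows and 35 libraries in columns, and a second table of normalized values. The deposited counts are whole numbers, and their totals ran from 34049751 to 72170489 per library. The normalized values (signal, not counts) were made by the authors by dividing the counts by 1 factor per library: these factors equalled DESeq2-type size factors computed from the counts, and the values differed from counts over factor by at most 0.000577. The normalized table was used for that check alone, and all tests used the counts. A deposited length column held multiples of 3 for 94.8% of genes, so it may give coding length for most genes, and it was not used. The 26 mutant columns of both tables name the allele R225ins, whereas the sample labels name it C240ins. Each column was matched to the sample with the same time, number and letter, and which allele name is right was not settled. No row carries the symbol ttpA, so the targeted gene was not analysed here and the genotype labels have no check from that gene. Symbols come from the tables, and 12728 of the 12865 identifiers matched a RefSeq gene table of assembly dicty_2.7, used for synonyms and for gene order.

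Groups follow the labels: WT at 0 h, 2 h and 6 h (n = 3 each), and mutant at 0 h (n = 9), 2 h (n = 8) and 6 h (n = 9). WT libraries carry a letter and mutant libraries a number (1, 2 or 4) and a letter, and the labels do not say what these stand for. The labels call the samples cultures, and p-values measure the spread between these cultures. If the mutant number marks a clone or a day, cultures that share it are not fully independent. At 2 h mutant libraries of the same number deviated together from their group mean (mean correlation 0.208, against -0.251 between numbers, one-sided exact permutation p = 0.00714, adjusted p = 0.0214 over 3 times). This was not detected at 0 h (adjusted p = 0.179) or at 6 h (adjusted p = 0.179). All 109 pairs of libraries within a group differed by more than sampling noise (lowest chi-square per degree of freedom 11.1), so none was counted as the same library deposited again. This does not show that the libraries of a group come from separate cultures.

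Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr by group, TMM factors scaled the libraries, and a quasi-likelihood model with 1 mean per group was tested with glmQLFTest. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called changed at an adjusted p under 0.05 with no minimum fold. The mutant against WT comparisons at 0 h and 6 h, the 6 h against 0 h comparisons in each genotype and the difference between those changes came from 1 fit of the 24 libraries at 0 h and 6 h (10992 genes tested, biological coefficient of variation 0.186). The 2 h comparison of the genotypes came from a fit of all 35 libraries (11131 genes, 0.174). The comparisons of 2 h with 0 h within each genotype were added after the data were seen and used that same fit. Every adjusted p given for a gene is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic, an approximation. Expression levels are CPM, counts scaled to a common library size with TMM factors over all 35 libraries, as mean ± SD over the libraries of a group. A total of 3 counts, taken as the floor, corresponds to between 0.0416 and 0.0881 CPM depending on the library. Principal components were computed from log2 CPM with a prior count of 2.

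A total of 23 gene lists were fixed by symbol before the data were examined: aggregation and cAMP signalling, discoidin and cell counting, prespore markers, prestalk markers, TIGER family, cytosolic ribosomal proteins, ribosome biogenesis, aminoacyl-tRNA synthetases, proteasome, autophagy, lysosomal hydrolases, DNA replication and cell cycle, chaperones, actin cytoskeleton, actin gene copies, mRNA decay factors, ABC transporters, polyketide synthases, G protein-coupled receptors, glycolysis and citric acid cycle, mitochondrial ribosomal proteins, histones, and transposable elements. Each was tested with camera (limma 3.58.1, preset correlation between genes of 0.01), with adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Members of the actin, histone, discoidin and transposable element lists share reads with near-identical copies, so values of single copies are uncertain.

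Named genes followed a rule fixed before the data were examined. In each comparison the rule took genes past the threshold with a mean of at least 10 CPM in either group and groups that did not overlap (the last condition was dropped for the difference of the changes), leaving out actin copies, transposable elements and pseudogenes. From these came the 6 largest rises, the 6 largest falls and the same number of each among genes with a symbol, and for each list described, up to 4 members with the largest change. A selection of these is named, with fixed genes given in every comparison of the fixed design: acaA, csaA, pdsA, regA, gpaB, tgrB1, tgrC1, cprD and mhcA. The fixed genes carA-1 and dscA-1 share reads with a second copy and are not described.

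Alternatives fixed before the data were examined were RLE and upper-quartile factors, DESeq2 1.42.0, no filter, a filter at 5 CPM, a 2-fold minimum, a replicate block, limma-voom with duplicateCorrelation, counts summed by mutant number, each mutant number left out or alone, each WT library left out, and fits of the compared groups alone. For mutant against WT at each time the block was the letter, and duplicateCorrelation used the mutant number within each time, with all WT libraries of a time as 1 block. For the other comparisons both used the full label (number and letter), so duplicateCorrelation did not account for the number there. Leaving out each mutant library was added later. The test was checked on simulated counts of independent cultures, drawn from the real means and library sizes with 200 changed genes. Far more genes were called in the real comparisons, so the simulated shares need not carry over to them. It recovered, of genes changed 2-fold, 83.3% for mutant against WT at 0 h, 71.2% at 2 h, 76.1% at 6 h, 69.7% for 6 h against 0 h in WT, 92.5% in the mutant and 56.7% for the difference of the changes. At 4-fold these shares were 97.0%, 93.8%, 100%, 89.4%, 98.5% and 93.8%. For 2 h against 0 h the shares at 2-fold were 72.7% in WT and 97.0% in the mutant. Unchanged genes made up 11.3% of the calls simulated for the difference of the changes, 6.62% for 6 h against 0 h in WT, 5.71% for 2 h against 0 h in WT and 5.49% for mutant against WT at 0 h, all above the 5% aimed at, and from 2.60% to 4.95% for the others.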

Results

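Transcript levels were measured by RNA sequencing in 35 cultures of Dictyostelium discoideum AX3 amebae, to ask how an insertion in ttpA changes the transcriptome during growth and over the first hours without nutrients. WT cultures were sequenced in triplicate at 0 h, 2 h and 6 h (n = 3 each), and mutant cultures at 0 h (n = 9), 2 h (n = 8) and 6 h (n = 9). Totals per library ran from 50057944 to 64485686 counts at 0 h, from 34049751 to 72170489 at 2 h and from 41747360 to 63209056 at 6 h. The lowest total was that of mutant library 1C at 2 h. The TMM factors differed between the genotypes. Their means were 0.849 ± 0.0316 in WT and 1.02 ± 0.0383 in the mutant at 0 h, 0.812 ± 0.0174 and 1.08 ± 0.0489 at 2 h, and 0.931 ± 0.0346 and 1.07 ± 0.0201 at 6 h (SD). With total counts alone, without these factors, the median log2 fold change of all genes between mutant and WT moved from near 0 to 0.28 at 0 h, 0.43 at 2 h and 0.21 at 6 h, and changes are reported relative to that median. Because the tables held no row named ttpA, the targeted gene was not analysed here, and the mutant is named after its labels.

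The first principal component, with 51.3% of the variance, followed the times, and the second, with 16.3%, separated the genotypes. On the first component WT libraries had mean scores of -16.0 at 0 h, -70.7 at 2 h and 67.6 at 6 h, so that the 0 h mean lay between those of the later times. Mutant libraries had means of 14.6, -61.7 and 46.6. The 9 mutant libraries at 0 h were the most spread out, from -5.53 to 41.9, against -19.0 to -10.5 for the WT libraries at 0 h. Mutant libraries 1A and 2B at 0 h (41.9 and 36.6) lay above the lowest mutant library at 6 h, 4C (30.7). On the second component the WT group means were -53.0, -45.7 and -38.2, and those of the mutant 14.9, 22.8 and 10.4.

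**Figure D1:**
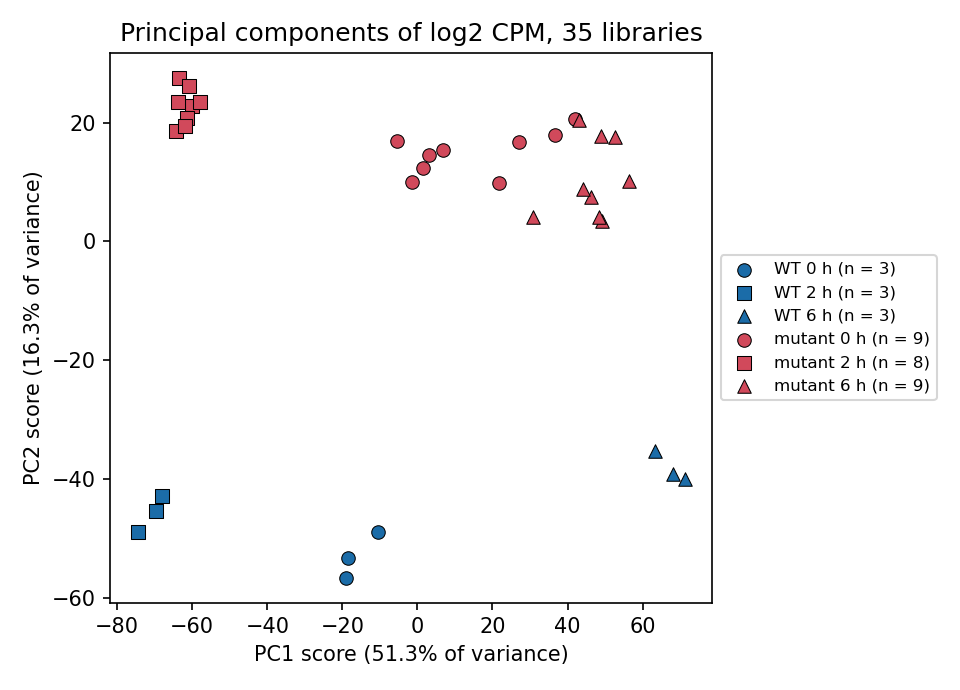
Scores of the 35 libraries on the first principal component (horizontal, 51.3% of variance) and the second (vertical, 16.3%), computed from log2 CPM. Blue marks WT and red the mutant, and circles, squares and triangles mark 0 h, 2 h and 6 h. The genotypes separate on the vertical axis. On the horizontal axis the 0 h means lie between those of 2 h and 6 h, and 2 mutant libraries at 0 h overlap the mutant libraries at 6 h.

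The comparison of mutant and WT at 0 h asked which transcripts differed before nutrients were withdrawn. Genes of aggregation, the step at which starving amebae stream together along waves of cAMP, were higher in the mutant cultures labelled 0 h than in WT. The adenylyl cyclase gene acaA averaged 461 ± 112 CPM in the mutant and 112 ± 38.3 CPM in WT (log2 fold change 2.04 ± 0.29 SE). The gene csaA, which codes for the adhesion glycoprotein contact site A, averaged 417 ± 94.8 against 111 ± 24.2 CPM (1.90 ± 0.26). The adhesion and kin recognition genes tgrB1 and tgrC1 averaged 72.03 ± 12.97 and 30.6 ± 8.03 CPM in the mutant against 15.2 ± 3.78 and 1.41 ± 1.06 CPM in WT. Without WT library A, the highest of the WT libraries at 0 h for tgrC1, the log2 fold change of tgrC1 was 5.25 instead of 4.43. Conversely, ribosomal protein genes, glycolytic genes and histone genes were lower in the mutant. With an estimated correlation the adjusted p was 0.256 for the aggregation list, 0.125 for ribosomal proteins, 0.414 for glycolysis and the citric acid cycle and 0.00766 for histones. In all, 5353 of 10992 genes differed, 2870 higher and 2483 lower in the mutant, of which 972 and 286 differed at least 2-fold.

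Of the 29 genes of the aggregation and cAMP signalling list, 20 were higher and 2 lower in the mutant at 0 h (21 and 3 when adjusted over the list alone). Among them was regA, an intracellular cAMP phosphodiesterase, at 645 ± 85.6 against 281 ± 63.7 CPM. The G protein alpha subunit gene gpaB averaged 721 ± 88.4 against 382 ± 34.3 CPM, and the cAMP receptor gene carC 6.53 ± 1.19 against 0.435 ± 0.0640 CPM. The secreted phosphodiesterase gene pdsA did not pass the test (1804 ± 284 against 1738 ± 82.7 CPM, adjusted p = 0.826). Nor did the cysteine protease gene cprD (452 ± 64.2 against 529 ± 33.8 CPM) or the myosin II heavy chain gene mhcA (adjusted p = 0.129 and 0.621). The list was higher by camera (adjusted p = 9.98e-07), a call that was lost with an estimated correlation (adjusted p = 0.256). Of 25 TIGER family genes, which code for cell surface proteins, 15 were higher and 1 lower (16 and 1 adjusted over the list alone). This call held with an estimated correlation (adjusted p = 0.0181). The family was weakly expressed, with a median log2 CPM from -0.77 to 0.27 in the mutant libraries at 0 h. It was not compared with other genes of like expression. In this family tgrR1 averaged 85.6 ± 15.5 CPM in the mutant and 5.38 ± 4.72 CPM in WT, with a log2 fold change of 3.98 that was 5.01 without WT library A. Of 8 prestalk marker genes 4 were higher and 2 lower, over all genes and adjusted over the list alone (camera adjusted p = 0.0350, and adjusted p = 0.125 with an estimated correlation). The ABC transporter and serine protease genes tagB and tagC averaged 22.6 ± 3.28 and 37.7 ± 4.82 CPM in the mutant against 5.44 ± 0.148 and 13.4 ± 1.30 CPM in WT. The Ras gene rasD was lower, at 9.14 ± 4.31 against 24.4 ± 4.49 CPM. ABC transporter genes were higher in 35 and lower in 6 of 65 (37 and 6 adjusted over the list alone, adjusted p = 0.226 with an estimated correlation).

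Named genes far above WT at 0 h included DDB_G0292248 (93.3 ± 22.8 against 2.19 ± 1.19 CPM, 42.3-fold), cbpA, a calcium-binding protein (129 ± 37.2 against 4.58 ± 2.14 CPM, 27.9-fold), and arkA (39.6 ± 4.69 against 1.40 ± 0.442 CPM, 27.9-fold). Others were psiI of the PSI protein family (254 ± 59.96 against 12.0 ± 10.4 CPM, 20.9-fold) and uduA3 (816 ± 168 against 39.7 ± 11.0 CPM, 20.4-fold). Without WT library A the log2 fold change of psiI was 5.39 instead of 4.39. In each of these 5 genes all 9 mutant libraries lay above all 3 WT libraries, which the naming rule required. A glycosidase of the lysosomal hydrolase list, nagD, averaged 18.6 ± 2.73 against 1.29 ± 0.357 CPM.

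All but 1 of the 79 cytosolic ribosomal protein genes, 78, were lower in the mutant at 0 h (79 adjusted over the list alone), with a median log2 fold change of -0.85 (camera adjusted p = 5.41e-45, and adjusted p = 0.125 with an estimated correlation). Of 29 genes of glycolysis and the citric acid cycle 20 were lower and 2 higher, also when adjusted over the list alone (adjusted p = 0.414 with an estimated correlation). They included gpdA, glyceraldehyde-3-phosphate dehydrogenase, at 1659 ± 244 against 3269 ± 291 CPM, and pfkA, phosphofructokinase, at 543 ± 144 against 1125 ± 57.7 CPM. The ATP citrate lyase gene acly averaged 197 ± 74.1 against 708 ± 59.0 CPM. Of 37 proteasome genes 24 were lower and 1 higher (25 and 1 adjusted over the list alone), with small changes such as that of psmA5 (-0.56 ± 0.09). Of 26 aminoacyl-tRNA synthetase genes 15 were lower and 1 higher (17 and 1 adjusted over the list alone). Both lists lost their camera call with an estimated correlation (adjusted p = 0.510 for each). Their counts also depended on the scaling. With total counts alone 6 proteasome genes were higher and 5 lower (median -0.018), and 1 synthetase gene was higher and 6 lower (median -0.17). Under that scaling the median of all genes was 0.28. Of 13 histone genes 10 were lower and 1 higher, also when adjusted over the list alone. This call held with an estimated correlation (adjusted p = 0.00766). H4a averaged 22.1 ± 4.93 CPM in the mutant and 742 ± 80.1 CPM in WT (-5.08 ± 0.21). H2AX averaged 160 ± 36.6 against 858 ± 125 CPM, and H3b 2.63 ± 0.484 against 59.9 ± 8.94 CPM. Histone copies can share reads, which makes values of single copies uncertain. The gene DDB_G0277323, next to H4a, averaged 0.738 ± 0.114 CPM in the mutant and 61.6 ± 7.82 CPM in WT (-6.39 ± 0.14). The gene rliB was also among the largest falls, at 28.7 ± 13.6 against 194 ± 17.1 CPM.

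At 2 h the question was whether the genotypes differed soon after the change of medium. Some aggregation genes were still higher in the mutant, at levels far below those of 0 h, and the low ribosomal protein and histone transcripts persisted (adjusted p = 0.196 and 0.00982 with an estimated correlation). The gene acaA averaged 13.4 ± 2.63 CPM in the mutant and 7.25 ± 0.423 CPM in WT (0.88 ± 0.26). The values were 17.3 ± 5.13 against 8.44 ± 1.39 CPM for csaA (1.03 ± 0.26) and 1.20 ± 0.273 against 0.441 ± 0.114 CPM for tgrC1. In all, 5533 of 11131 genes differed, 2749 higher and 2784 lower, of which 1086 and 290 differed at least 2-fold. With upper-quartile factors 62.4% of the called genes were higher, against 49.7% with TMM factors, so the balance of directions depends on the scaling.

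Of the 29 aggregation genes 11 were higher and 4 lower at 2 h, also when adjusted over the list alone, and the list as a whole did not pass camera (adjusted p = 0.354). The gene regA averaged 191 ± 14.8 against 142 ± 13.9 CPM and tgrB1 27.5 ± 2.17 against 16.6 ± 4.57 CPM. The genes gpaB and pdsA did not pass the test (178 ± 14.7 against 182 ± 19.96 CPM, and 349 ± 52.7 against 312 ± 15 CPM), nor did mhcA (adjusted p = 0.507), while cprD was lower (-0.40 ± 0.12). Without WT library B at 2 h neither regA nor cprD passed (adjusted p = 0.0591 and 0.115). Of 27 TIGER family genes 23 were higher and 1 lower, also adjusted over the list alone. This held with an estimated correlation (adjusted p = 0.0101). Of 39 polyketide synthase genes 26 were higher and 1 lower, also adjusted over the list alone (adjusted p = 0.329 with an estimated correlation), among them pks2 at 76.3 ± 14.4 against 18.9 ± 3.67 CPM. The named genes furthest above WT included 4 of the same name family, uduA1, uduA2, uduA3 and uduB, which were 20.3-fold, 24.2-fold, 19.6-fold and 17.5-fold higher. Others were arkA (22.2 ± 2.03 against 1.11 ± 0.193 CPM), the srfA-induced gene sigB (54.8 ± 3.63 against 3.98 ± 0.557 CPM) and DDB_G0293610 (15.7 ± 1.80 against 0.704 ± 0.0689 CPM).

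Lower in the mutant at 2 h were 78 of 79 cytosolic ribosomal protein genes, with none higher, over all genes and adjusted over the list alone (median -0.98, and adjusted p = 0.196 with an estimated correlation). Examples were rpl19 at 2499 ± 516 against 6037 ± 646 CPM and rpl22 at 381 ± 91.7 against 942 ± 105 CPM. Of 39 genes of DNA replication and the cell cycle 26 were lower and none higher (27 and none adjusted over the list alone, adjusted p = 0.430 with an estimated correlation). Among them cdc45, a part of the replicative helicase, the polo-like kinase gene plk and the clamp loader gene rfc4 had log2 fold changes of -1.21, -1.07 and -1.22. Of 13 histone genes 11 were lower, also adjusted over the list alone. This held with an estimated correlation (adjusted p = 0.00982). The median log2 fold change of the list was -0.91 and the mean -2.03, with H4a, H3b and H3c at -4.92, -4.88 and -7.21. The list was not tested without these copies. H4a averaged 22.8 ± 9.16 against 689 ± 104 CPM. Of 50 actin cytoskeleton genes 26 were lower and 4 higher, also adjusted over the list alone (adjusted p = 0.196 with an estimated correlation). With total counts alone the median of the list was positive, at 0.12, but still below that of all genes, 0.43. In that list ctxB, coding for the actin-bundling cortexillin II, averaged 501 ± 28.7 against 995 ± 65.0 CPM. The unconventional myosin gene myoH was higher, at 23.98 ± 2.76 against 3.46 ± 0.273 CPM. The folate receptor gene far1 averaged 104 ± 7.69 against 279 ± 37.9 CPM, and grp94, a chaperone of the endoplasmic reticulum, 528 ± 74.8 against 1014 ± 98.3 CPM.

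At 6 h the comparison asked how the genotypes differed once starvation was established. Transcripts of the ribosome biogenesis and replication lists were higher in the mutant, and those of the proteasome lower. These list calls were lost with an estimated correlation (adjusted p = 0.415 for ribosome biogenesis, 0.201 for replication and 0.201 for the proteasome). All 27 ribosome biogenesis genes were higher in the mutant, over all genes and adjusted over the list alone (median log2 fold change 1.22). Examples were utp15 at 7.15 ± 1.58 against 2.14 ± 0.336 CPM, wdr12 at 11.5 ± 2.74 against 3.96 ± 0.830 CPM and nol1 at 18.1 ± 5.16 against 6.06 ± 1.46 CPM. Of 38 replication and cell cycle genes 32 were higher and 2 lower, also adjusted over the list alone. They included cdc45 at 28.4 ± 4.52 against 8.37 ± 1.80 CPM, the thymidylate synthase gene thyA at 81.8 ± 10.6 against 26.4 ± 5.14 CPM and the helicase gene mcm4 at 20.1 ± 3.07 against 6.69 ± 1.69 CPM. In all, 5113 of 10992 genes differed, 2573 higher and 2540 lower, of which 877 and 428 differed at least 2-fold. With upper-quartile factors 63.1% of the called genes were higher, against 50.3% with TMM factors. With the mutant cultures of a single number, 4149 genes were called for number 1, 3372 for number 2 and 6456 for number 4.

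Of 37 proteasome genes 33 were lower and 1 higher (35 and 1 adjusted over the list alone, adjusted p = 0.201 with an estimated correlation), with psmD13 and psmD4 at log2 fold changes of -0.83 and -0.78. Of 79 cytosolic ribosomal protein genes 67 were lower and none higher (69 and none adjusted over the list alone, median -0.43, adjusted p = 0.475 with an estimated correlation), with rpl19 at 1793 ± 156 against 3044 ± 324 CPM. Of the 29 aggregation genes 2 were higher and 10 lower, also adjusted over the list alone, and the list did not pass camera (adjusted p = 0.135). The values of acaA (541 ± 173 against 739 ± 83.3 CPM, adjusted p = 0.136), csaA (249 ± 80.8 against 354 ± 45.0 CPM, adjusted p = 0.0652) and regA (730 ± 138 against 890 ± 39.4 CPM) did not pass the test. Nor did those of gpaB (782 ± 148 against 920 ± 66.3 CPM), tgrB1 (33.5 ± 6.13 against 26.3 ± 3.29 CPM) and tgrC1 (11.2 ± 4.09 against 6.92 ± 1.64 CPM). The genes pdsA and cadA, the latter coding for a calcium-dependent adhesion protein, were lower (-0.43 ± 0.15 and -0.80 ± 0.23), as were cprD (-0.41 ± 0.13) and mhcA (-0.32 ± 0.11). Without WT library C at 6 h pdsA, cprD and mhcA did not pass (adjusted p = 0.125, 0.0818 and 0.111), nor did pdsA without B (0.126) or mhcA without A or B (0.0572 and 0.0725). Autophagy genes were lower in 7 and higher in 1 of 16, also adjusted over the list alone, and the list did not pass camera (adjusted p = 0.0730). The kinase gene atg1 and the genes atg9 and atg18 had log2 fold changes of -0.65, -0.54 and -0.50. Of 25 TIGER family genes 5 were higher and none lower (4 and none adjusted over the list alone). Unlike at 0 h and 2 h, this list did not pass camera (adjusted p = 0.0687).

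Named genes far above WT at 6 h were DDB_G0278219 (52.8 ± 5.18 against 5.66 ± 0.822 CPM), DDB_G0279211 (286 ± 66.4 against 32.6 ± 5.61 CPM), arkA (20.7 ± 4.91 against 3.52 ± 0.425 CPM) and dcd2B (28.1 ± 3.35 against 5.81 ± 0.657 CPM). The superoxide dismutase gene sodC (2089 ± 338 against 512 ± 16.5 CPM) was also high, as were the pyrimidine synthesis genes pyr1-3 (149 ± 61.98 against 33.2 ± 5.62 CPM) and pyr56 (18.6 ± 6.39 against 4.71 ± 1.06 CPM). Far below WT were DDB_G0293242 (15.5 ± 5.55 against 171 ± 33.0 CPM), iliG (33.5 ± 6.77 against 305 ± 18.5 CPM) and psiB (3.32 ± 0.702 against 23.0 ± 2.12 CPM). The same held for the frizzled-like receptor gene fslP (1.78 ± 0.7095 against 14.7 ± 1.73 CPM) and rasD (6.28 ± 2.38 against 28.6 ± 4.99 CPM). H4a, H3b and DDB_G0277323 were again low, with log2 fold changes of -4.63, -4.37 and -5.77. Of 13 histone genes 6 were lower and 1 higher at 6 h (8 and 1 adjusted over the list alone). Unlike at 0 h and 2 h, the camera call of this list was lost with an estimated correlation (adjusted p = 0.116).

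**Figure D2:**
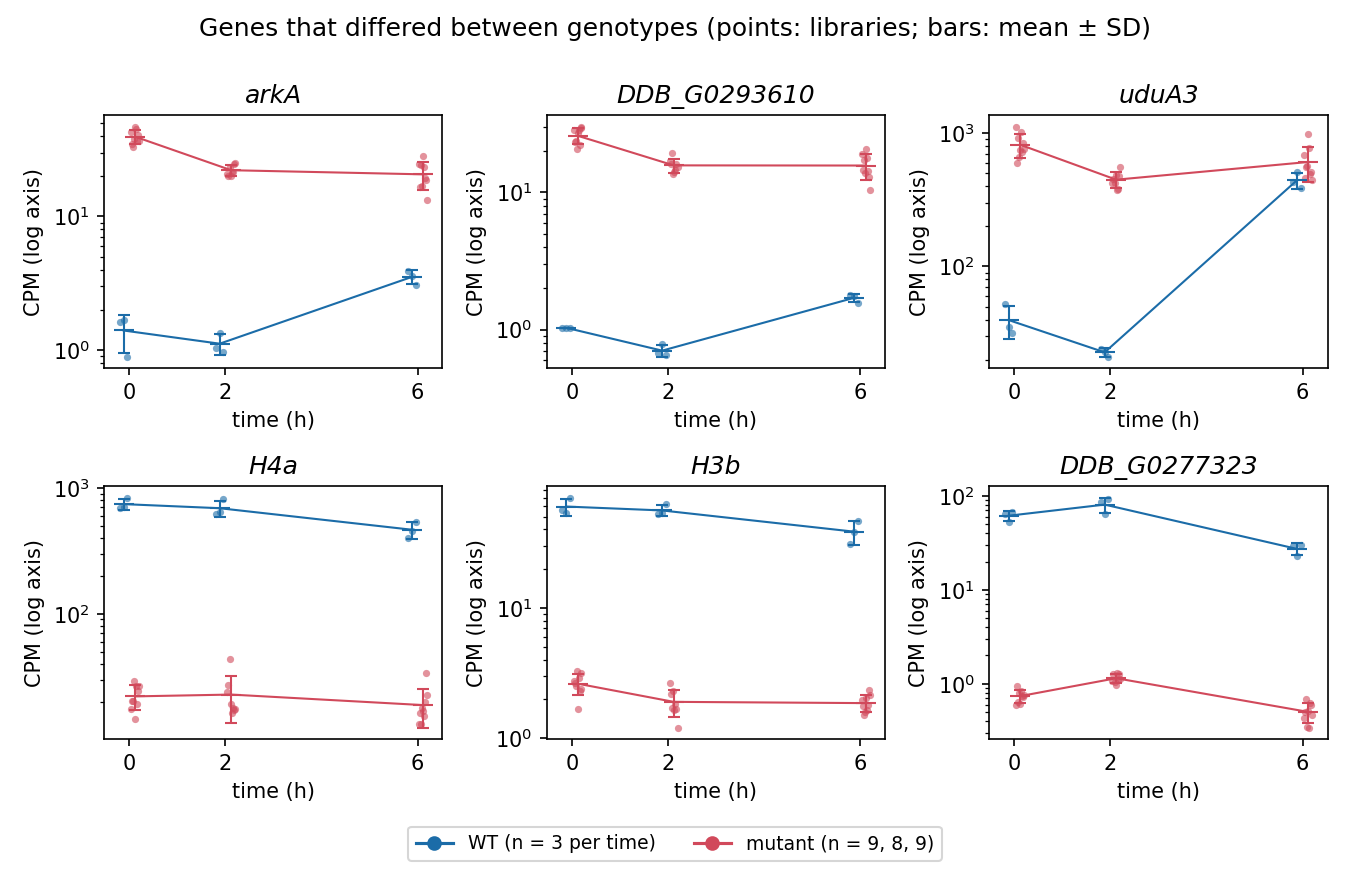
CPM (log axis) against hours without nutrients for arkA, DDB_G0293610, uduA3, H4a, H3b and DDB_G0277323. Points are libraries and bars are group means ± SD, in blue for WT (n = 3 per time) and red for the mutant (n = 9, 8 and 9). At 0 h the means of H4a are 742 CPM in WT and 22.1 CPM in the mutant, and those of uduA3 in WT are 39.7 CPM at 0 h, 22.8 CPM at 2 h and 441 CPM at 6 h.

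Across the 10992 genes tested at both times, the mutant against WT changes at 0 h and at 6 h correlated with Pearson's r = 0.449 and Spearman's rank correlation = 0.314, a correlation across genes, which are not independent replicates. Calls in both comparisons were higher for 1039 genes and lower for 945, where independent lists would share 672 and 574, while 647 genes were called in opposite directions. The 2 comparisons share no library. Between 0 h and 2 h r was 0.730, and between 2 h and 6 h it was 0.387. Higher in the mutant at all 3 times were 689 genes and lower 696, where independent lists would share 165 and 145.

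Changes from 0 h to 2 h were compared within each genotype after the data had been seen. The genes acaA, csaA, pdsA, regA, gpaB and tgrC1 had their lowest level at 2 h in both genotypes, while tgrB1 did not pass the test in WT (15.2 ± 3.78 and 16.6 ± 4.57 CPM). In WT acaA dropped from 112 ± 38.3 to 7.25 ± 0.423 CPM, csaA from 111 ± 24.2 to 8.44 ± 1.39 CPM and pdsA from 1738 ± 82.7 to 312 ± 15 CPM. In the mutant acaA dropped from 461 ± 112 to 13.4 ± 2.63 CPM, csaA from 417 ± 94.8 to 17.3 ± 5.13 CPM and tgrC1 from 30.6 ± 8.03 to 1.20 ± 0.273 CPM. In WT tgrC1 did not pass the test without library A at 0 h (adjusted p = 0.203, and 0.00692 with it). Of the 29 aggregation genes 16 fell and 2 rose in WT, and 24 fell and 4 rose in the mutant, also adjusted over the list alone (adjusted p = 0.870 and 0.199 with an estimated correlation). Genes of ribosome biogenesis rose in 11 of 27 in WT and in 20 of 27 in the mutant, where 1 fell. Those of glycolysis and the citric acid cycle rose in 12 of 29 in WT, where 1 fell, and in 20 of 29 in the mutant, where 2 fell. Both lists had the same counts adjusted over the list alone. These calls were also lost with an estimated correlation (adjusted p = 0.895 and 0.879 for biogenesis, 0.870 and 0.879 for glycolysis). In all, 4095 of 11131 genes changed in WT, 2003 higher and 2092 lower at 2 h, of which 281 and 884 changed at least 2-fold. In the mutant 7786 changed, 3835 higher and 3951 lower, of which 633 and 1149 changed at least 2-fold. With fewer WT cultures, simulated 1.5-fold changes were recovered in 37.3% of genes in WT and 84.6% in the mutant. The counts above, for lists and for all genes, thus do not compare the size of the response between genotypes. The SD of the log2 fold changes over all genes was 0.823 in WT and 0.872 in the mutant.

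Among the largest falls from 0 h to 2 h in both genotypes were fslK (47.5 ± 15.01 to 1.35 ± 0.141 CPM in WT and 57.2 ± 18.2 to 1.38 ± 0.318 CPM in the mutant) and tmcC (449 ± 159 to 14.7 ± 1.18 CPM and 467 ± 182 to 13.3 ± 0.955 CPM). Large falls in the mutant were also those of psiI (254 ± 59.96 to 3.42 ± 0.397 CPM) and cfrB (701 ± 119 to 23.7 ± 5.54 CPM). The largest rises included the surface glycoprotein gene gp130 (73.5 ± 5.84 to 260 ± 43.2 CPM in WT), the pyrimidine synthesis gene pyr1-3 (280 ± 47.2 to 886 ± 24.97 CPM), the histidine kinase gene dhkJ (5.74 ± 0.382 to 21.9 ± 3.34 CPM) and dduA (21.1 ± 1.04 to 101 ± 19.7 CPM). Each of these 4 also rose in the mutant. In WT gp130 did not pass without library A or C at 0 h (adjusted p = 0.0578 and 0.0594). The alternative oxidase gene aoxA rose in the mutant from 91.1 ± 40.5 to 487 ± 78.8 CPM. The changes of the genotypes correlated across genes with r = 0.752. With upper-quartile factors 61.4% of the genes called in the mutant were higher at 2 h, against 49.3% with TMM factors, and the median of all genes lay at 0.13 on the log2 scale.

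**Figure D3:**
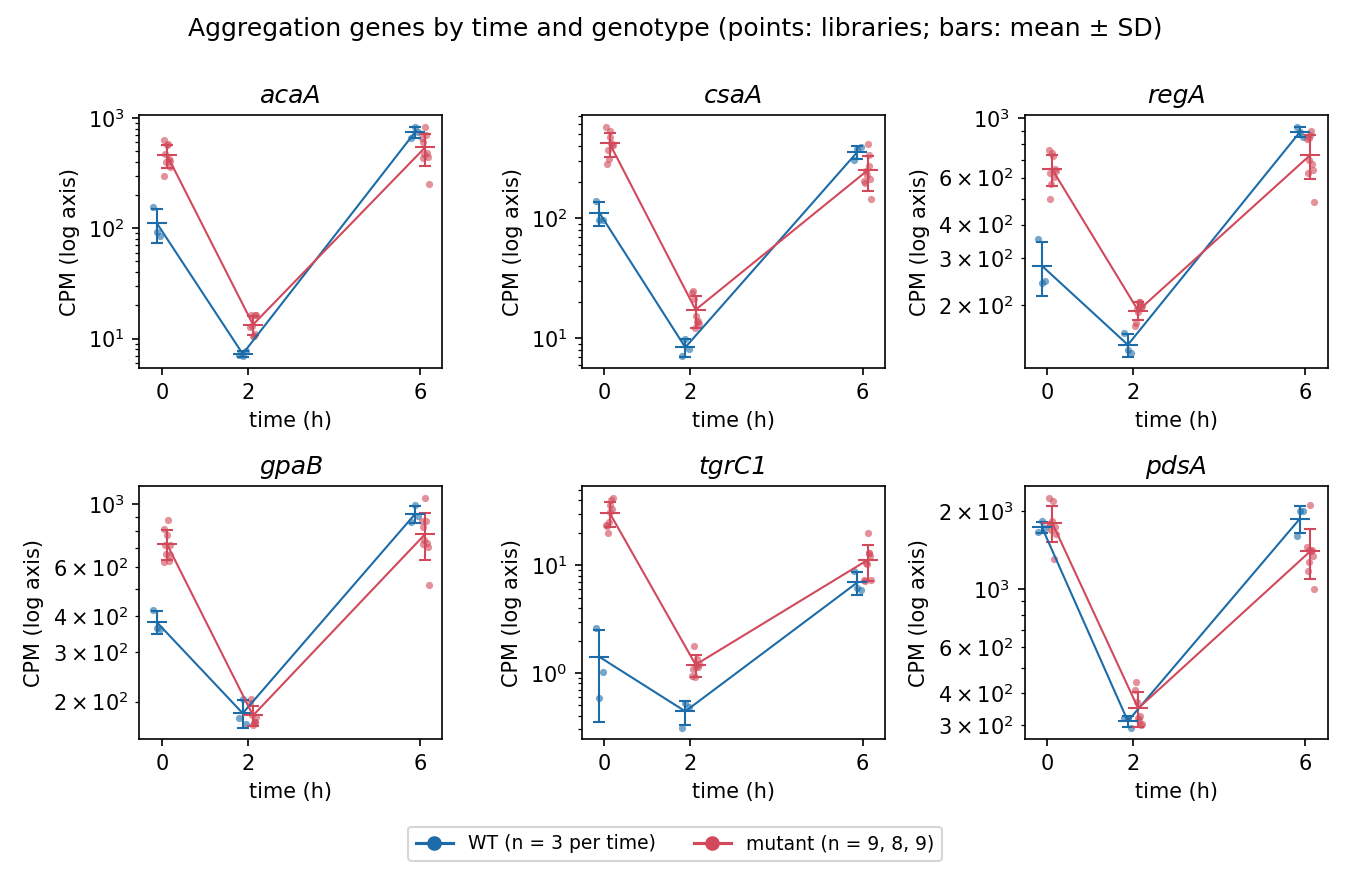
CPM (log axis) against hours without nutrients for 6 aggregation genes. Points are libraries and bars are group means ± SD, in blue for WT (n = 3 per time) and red for the mutant (n = 9, 8 and 9). The mean of acaA is 112 CPM in WT and 461 CPM in the mutant at 0 h, 7.25 and 13.4 CPM at 2 h, and 739 and 541 CPM at 6 h.

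The comparison of 6 h with 0 h in WT gave the response of unmutated amebae to starvation. Among aggregation genes acaA rose from 112 ± 38.3 to 739 ± 83.3 CPM (2.73 ± 0.33) and csaA from 111 ± 24.2 to 354 ± 45.0 CPM. The increase was also seen in regA, from 281 ± 63.7 to 890 ± 39.4 CPM, gpaB, from 382 ± 34.3 to 920 ± 66.3 CPM, tgrC1, from 1.41 ± 1.06 to 6.92 ± 1.64 CPM, and tgrB1 (0.80 ± 0.21). Without WT library A at 0 h the log2 fold change of tgrC1 was 3.11 instead of 2.31. Genes of ribosome biogenesis and of the cytosolic ribosome fell, with every one of the 27 ribosome biogenesis genes and 78 of the 79 cytosolic ribosomal protein genes lower at 6 h. Both list calls had an adjusted p of 0.506 with an estimated correlation. In all, 6868 of 10992 genes changed, 3632 higher and 3236 lower, of which 1326 and 1410 changed at least 2-fold. With upper-quartile factors 44.4% of the called genes were higher, against 52.9% with TMM factors.

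Of the 29 aggregation genes 23 rose and 1 fell in WT, also adjusted over the list alone, and pdsA did not pass the test (1738 ± 82.7 to 1872 ± 226 CPM). Of 16 autophagy genes 10 rose and 1 fell and of 41 lysosomal hydrolase genes 21 rose and 7 fell, also adjusted over the list alone. Among these, atg8a went from 152 ± 2.18 to 298 ± 35.8 CPM and atg1 from 31.6 ± 1.94 to 60.9 ± 3.05 CPM. The cysteine protease genes cprF and cprD went from 144 ± 13.8 to 599 ± 52.4 CPM and from 529 ± 33.8 to 1115 ± 75.2 CPM. The aggregation call had an adjusted p of 0.506 with an estimated correlation, and those of autophagy and lysosomal hydrolases 0.478. Large rises were those of DDB_G0285623 (33.95-fold), uduA2 (16.5-fold), cnrG (12.6-fold), uduA3 (11.2-fold) and prtA (10.6-fold). Others were the ABC transporter genes abcA7 (10.3-fold) and abcA8 (9.45-fold) and the kinase gene vwkA (9.52-fold). The spore coat gene cotD rose 3.66-fold, but of the 9 prespore genes 2 rose and 1 fell, also adjusted over the list alone, and the list did not pass camera (adjusted p = 0.728). Of 13 genes of the discoidin and cell counting list 5 rose and 2 fell, also adjusted over the list alone, among them cinC (4.32-fold higher) and cinB (2.88-fold higher), and the list did not pass camera (adjusted p = 0.362).

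Of 38 replication and cell cycle genes 25 fell and 3 rose in WT. Of 29 genes of glycolysis and the citric acid cycle 21 fell and 1 rose, and of 24 mitochondrial ribosomal protein genes 12 fell and 1 rose. In each case the counts were the same adjusted over the list alone. Examples were thyA (118 ± 7.92 to 26.4 ± 5.14 CPM), rfc2 (32.1 ± 0.564 to 8.22 ± 1.24 CPM) and the malate dehydrogenase gene mdhB (1866 ± 222 to 660 ± 32.6 CPM). Others were pfkA (1125 ± 57.7 to 402 ± 18.6 CPM), tpiA (133 ± 8.07 to 47.1 ± 2.52 CPM) and mrpl13 (58.5 ± 3.87 to 18.1 ± 0.501 CPM). These calls all had an adjusted p of 0.506 with an estimated correlation. Chaperone genes fell in 15 of 39 and rose in none (14 adjusted over the list alone, adjusted p = 0.506 with an estimated correlation), with hspK going from 157 ± 14.3 to 20.9 ± 1.68 CPM. The largest falls were those of DDB_G0268878 (934 ± 106 to 12.3 ± 3.82 CPM), gp130 (73.5 ± 5.84 to 3.08 ± 0.812 CPM) and acly (708 ± 59.0 to 32.3 ± 4.62 CPM). Others were the srfA-induced gene sigJ (18.9 ± 10.4 to 0.871 ± 0.125 CPM) and the polyketide synthase gene pks16 (1085 ± 23.8 to 85.0 ± 15.5 CPM). The level of mhcA did not pass the test (5838 ± 411 and 5652 ± 172 CPM).

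The same comparison in the mutant gave 6032 changed genes, 3002 higher and 3030 lower, of which 370 and 601 changed at least 2-fold. The SD of the log2 fold changes over all genes was 0.617 in the mutant and 1.02 in WT, and r between them was 0.647 across genes. The aggregation list did not move one way, with 6 genes higher and 7 lower, also adjusted over the list alone (camera adjusted p = 0.549). The levels of acaA (461 ± 112 and 541 ± 173 CPM), regA (645 ± 85.6 and 730 ± 138 CPM) and gpaB (721 ± 88.4 and 782 ± 148 CPM) did not pass the test. The genes csaA, tgrB1, tgrC1 and cadA fell, with log2 fold changes of -0.73, -1.10, -1.44 and -1.96, as did pdsA and mhcA (-0.35 and -0.43), and cprD rose (0.91). Genes that charge tRNAs rose in 19 of 26 and fell in 2 (20 and 2 adjusted over the list alone, adjusted p = 0.416 with an estimated correlation). In WT 16 rose and 5 fell (16 and 6 adjusted over the list alone), the list did not pass camera (adjusted p = 0.227), and its difference between the genotypes did not pass either (adjusted p = 0.147). In the mutant leuS rose from 430 ± 29.3 to 1023 ± 344 CPM, trpS from 175 ± 31.0 to 416 ± 156 CPM and valS1 from 229 ± 24.2 to 521 ± 165 CPM. With the mutant cultures of a single number, 2120 genes changed for number 1, 2670 for number 2 and 6003 for number 4.

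Ribosomal protein genes fell in 67 of 79 in the mutant (68 adjusted over the list alone), and proteasome genes in 33 of 37 with 1 higher, also adjusted over the list alone. Genes of glycolysis and the citric acid cycle fell in 23 of 29 with 1 higher (24 and 1 adjusted over the list alone). The p with an estimated correlation was 0.416 after adjustment in each. Examples were rps29 (322 ± 62.03 to 204 ± 23.4 CPM), rpl39 (536 ± 92.9 to 316 ± 27.6 CPM), psmD10 (26.9 ± 3.75 to 15.4 ± 1.44 CPM), psmD11 (193 ± 31.9 to 122 ± 15.6 CPM) and mdhB (946 ± 203 to 569 ± 35.4 CPM). Replication and cell cycle genes, by contrast, rose in 24 of 38 and fell in 2, also adjusted over the list alone (adjusted p = 0.569 with an estimated correlation). The gene polA2 went from 28.2 ± 7.23 to 63.2 ± 13.6 CPM and cdc45 from 17.5 ± 4.02 to 28.4 ± 4.52 CPM. Autophagy genes rose in 8 of 16 with none lower, also adjusted over the list alone (adjusted p = 0.416 with an estimated correlation), including atg8a (1.44-fold) and atg9 (1.37-fold). Large changes common to both genotypes were the rises of DDB_G0285623, abcA7 and abcA8 (22.7-fold, 6.01-fold and 6.17-fold in the mutant) and the falls of DDB_G0268878 and acly (226 ± 160 to 4.50 ± 2.21 CPM and 197 ± 74.1 to 34.4 ± 4.23 CPM).

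The test of the difference asked whether the change from 0 h to 6 h itself depended on the genotype. Aggregation genes rose in WT, whereas in the mutant 6 rose and 7 fell of 29. Every ribosome biogenesis gene fell in WT, against 2 higher and 1 lower of 27 in the mutant, and replication genes mostly fell in WT and mostly rose in the mutant. The list calls of these changes were lost with an estimated correlation (adjusted p = 0.506 for each list in WT and 0.569 for replication in the mutant). The log2 fold change of acaA from 0 h to 6 h was 2.73 in WT and 0.24 in the mutant, a difference of -2.49 ± 0.37. That of csaA was 1.68 and -0.73, a difference of -2.42 ± 0.34. Both genes were higher in the mutant at 0 h and did not pass the test between the genotypes at 6 h. In tgrC1 the changes were 2.31 and -1.44, and in uduA3 3.48 and -0.42. In all, 4209 of 10992 genes had a different change, 1987 with a more positive change in the mutant and 2222 with a more negative one, of which 739 and 742 differed at least 2-fold. Of the 2222 genes, 914 differed between the genotypes at 0 h only, 705 at 6 h only and 541 at both times. Of the 1987 genes, these counts were 617, 769 and 524. With upper-quartile factors 58.8% of the called genes were more positive, against 47.2% with TMM factors.

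Of the 29 aggregation genes 21 had a more negative change in the mutant and none a more positive one (22 adjusted over the list alone, adjusted p = 0.247 with an estimated correlation). The fixed genes regA, gpaB and tgrB1 differed by -1.49 ± 0.22, -1.15 ± 0.19 and -1.90 ± 0.24, and pdsA, cprD and mhcA did not pass the test (adjusted p = 0.0915, 0.462 and 0.0536). All 27 ribosome biogenesis genes had a more positive change, over all genes and adjusted over the list alone (median difference 1.53, adjusted p = 0.433 with an estimated correlation). Among them utp15, wdr12 and nola1 had differences of 2.13, 1.94 and 1.91. Of 38 replication and cell cycle genes 26 were more positive and 1 more negative (29 and 1 adjusted over the list alone, adjusted p = 0.247 with an estimated correlation). The log2 fold changes in WT and mutant were -1.62 and 0.71 for cdc45, -2.14 and 0.11 for thyA and -1.50 and 0.43 for polA3. The difference was also positive for 47 of 79 cytosolic ribosomal protein genes (64 adjusted over the list alone, adjusted p = 0.665 with an estimated correlation) and 11 of 24 mitochondrial ones (14 adjusted over the list alone, adjusted p = 0.477 with an estimated correlation), with none more negative. It was negative for 18 of 37 proteasome genes with none more positive (20 adjusted over the list alone, adjusted p = 0.691 with an estimated correlation). Genes of nucleotide synthesis and salvage, pyr1-3, pyr56 and hprT, fell in WT by 3.07, 3.08 and 2.996 on the log2 scale and had log2 fold changes of -0.22, -0.34 and -0.34 in the mutant. The genes gppA, psiI and nagD rose in WT (2.67, 2.41 and 1.90) and fell in the mutant (-1.12, -1.19 and -1.08). Without WT library A at 0 h the differences of tgrC1, psiI and gppA were -4.555, -4.59 and -4.47, against -3.75, -3.60 and -3.79.

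**Figure D4:**
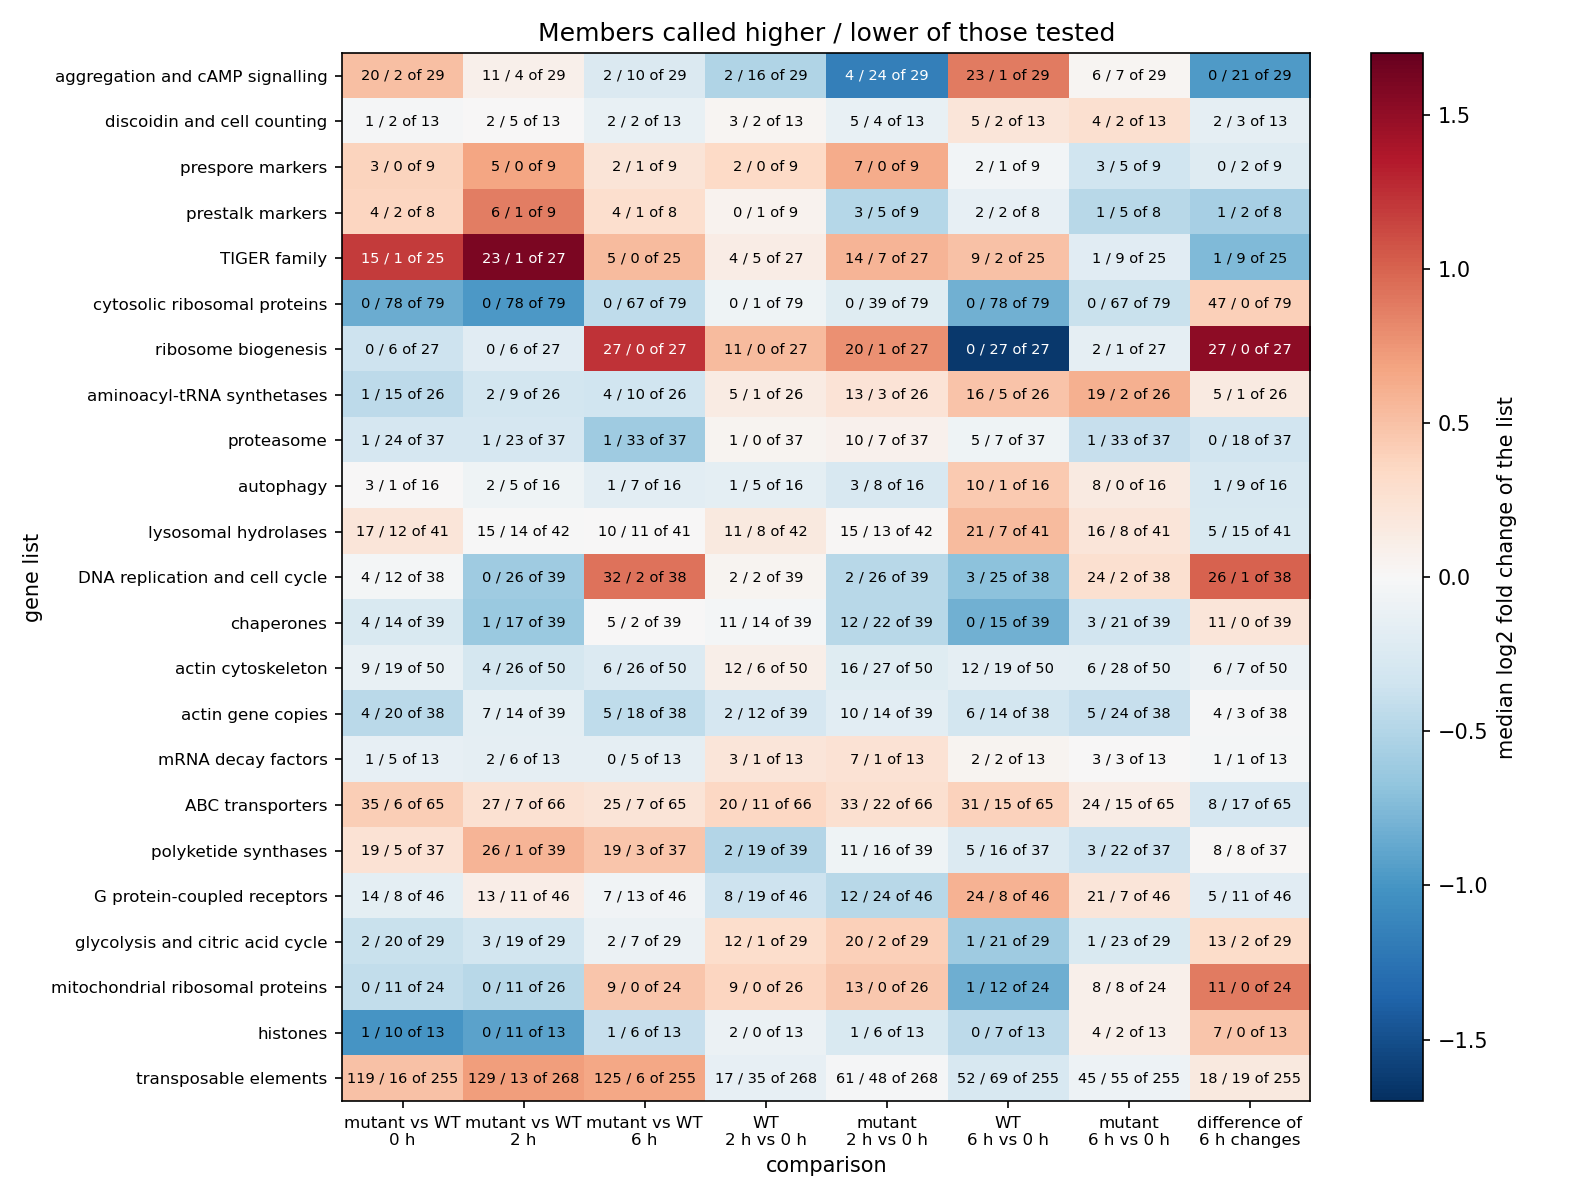
The 23 gene lists (rows) in 8 comparisons (columns), with the number of members called higher and lower of those tested in each cell, and the median log2 fold change of the list as colour, red above 0 and blue below. In the first column 20 of 29 aggregation genes are higher and 78 of 79 cytosolic ribosomal protein genes lower, and in the third column all 27 ribosome biogenesis genes are higher.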

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

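Of the tests described here, that on a later culture state was set down before its result was seen, and the others, the counts of splits among them, after. The change from 0 h to 6 h differed between mutant and WT in 4209 genes, by a test of the difference itself. Only 1 of 100 splits of the same libraries, the real one, gave as many, and the highest of the others gave 2979. These splits exchanged genotype labels within each time and so took the genotypes to be alike at both times. The genotypes differed at each time, so the splits cannot decide whether the difference of the changes arose by chance. The 10 lists with a different change by camera had median differences (log2, mutant minus WT) of -0.96 for aggregation and cAMP signalling, -0.75 for the TIGER family, 0.40 for cytosolic ribosomal proteins, 1.53 for ribosome biogenesis, -0.32 for the proteasome, 1.002 for DNA replication and cell cycle, 0.21 for chaperones, 0.32 for glycolysis and the citric acid cycle, 0.89 for mitochondrial ribosomal proteins and 0.47 for histones. None of these calls held with an estimated correlation (adjusted p from 0.247 to 0.790).

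Genes with a more positive change in the mutant than in WT were DDB_G0268158 (difference 3.08), dduA (2.90), pyr1-3 (2.85), pyr56 (2.73), hprT (2.65), pks16 (2.41), cdc45 (2.33), thyA (2.26), utp15 (2.13), wdr12 (1.94), polA3 (1.93), nola1 (1.91) and mrpl13 (1.55). Genes with a more negative change were DDB_G0292248 (-3.90), uduA3 (-3.90), gppA (-3.79), tgrC1 (-3.75), uduA2 (-3.74), psiI (-3.60), nagD (-2.98), acaA (-2.49), csaA (-2.42), tgrB1 (-1.90), cprF (-1.51), regA (-1.49), gpaB (-1.15), atg18 (-0.87), atg1 (-0.71) and psmD1 (-0.70).

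A single library stood apart from the rest of its group in 6 of 111 groups of values examined, where chance gives about 5.55. These were groups of mutant libraries, since the WT groups of 3 are too small for this test. Mutant library 2B at 6 h had the highest pdsA level (2112 CPM, others 1001 to 1461), the highest tgrC1 level (20.1 CPM, others 7.06 to 13.0) and the highest median log2 CPM of the aggregation list (7.60, others 7.06 to 7.27). In mutant library 1C at 2 h, which had the lowest total, the median log2 CPM of the mitochondrial ribosomal protein genes was 2.21 (others 0.38 to 1.14). Mutant library 4C at 6 h had a median of 1.63 for the prespore list (others 1.88 to 2.10), and mutant library 1A at 6 h one of 3.41 for the actin gene copies (others 4.20 to 4.78). Leaving out mutant library 2B at 6 h gave 5196 genes for mutant against WT at 6 h, and 3 of 109 results for named genes newly passed the test.

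For the high aggregation transcripts of the mutant at 0 h, normalization factors, which move all genes of a library alike, are argued against as the whole cause in these libraries: the median log2 fold change of the list lay 0.505 above that of all genes, and the highest of 10000 random lists of like expression lay 0.389 above it. Random lists lack the correlation between the members, and with an estimated correlation the call of the list was lost (adjusted p = 0.256). A single wrongly labelled library is also argued against as the source of these high levels, because in 19 of the 20 members called higher every mutant library lay above every WT library. These members were chosen by their calls in the same libraries. The separation cannot show whether any library carries a wrong time label. A later state of the mutant cultures at harvest stays open: across 10963 genes outside the list, the change at 0 h correlated at 0.365 with the WT change from 2 h to 6 h, which shares no library with it, and removing the fitted line lowered the list's median from 0.51 to 0.26. Whether such a state may come from the insertion or from differences in density or handling between cultures was not tested, and the genotype remains open as a biological explanation.

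A set of 11 genes, of which H4a, H3b and H3c are histone genes, was at least 4-fold lower in the mutant at 0 h, 2 h and 6 h. For H4a, reads moved to the other H4 copy are argued against, since the summed copies also fell, with a log2 ratio of mutant to WT of -3.49 at 0 h. For H3b and H3c this stays open: the summed H3 copies fell too (-0.63), beyond the bound set, but the set's copies made up only 5.91% of that sum in WT, so it cannot decide. A genome difference that removes or silences neighbouring genes could account for part of the set: 5 pairs of the 11 genes lay within 5 genes of one another in the reference order, where random sets of the same size had a median of 0 and at most 2 (permutation p = 1e-04, the smallest that 10000 draws can give). These were H3b with H3c, H4a with DDB_G0277323, and the trio of DDB_G0288219, DDB_G0288221 and DDB_G0288233, chosen after their values were seen, but genes at least 4-fold higher at all times were also grouped, with 13 such pairs among 63 placed genes against at most 8 in random sets, so that nearness alone does not single out a genome difference, and regulation shared by neighbours stays open. In the mutant at 0 h the trio averaged 12.9 ± 5.83, 2.53 ± 1.24 and 1.46 ± 0.722 CPM, above the floor. Each of these genes was lower at 2 h and higher again at 6 h, as in WT. These values argue against complete removal of the trio, while silencing stays open.

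The fall of many aggregation transcripts from 0 h to 2 h in both genotypes, before their level at 6 h, raises the question of the time labels. An exchange of 0 h and 2 h in a single genotype is argued against by the correlation of 0.752 between the genotypes' changes from 0 h to 2 h. An exchange in both genotypes is not excluded: of 4008 genes at least 2-fold different between 2 h and 6 h in WT, 87.0% had their 0 h mean in between, and in the mutant 84.2% of 2787 (of the aggregation list, 19 of 19 such members in WT and 12 of 18 in the mutant). The same order could arise if nearly confluent cultures had begun the starvation programme and the change of medium set it back, for which the design has no control. Every comparison with 0 h or 2 h depends on these labels.

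For the other comparisons, the real split of the cultures gave the most called genes. If the cultures are independent, chance is argued against for mutant against WT at 0 h (1 of 100 splits, 5029 genes in a fit of these libraries alone against at most 1011 in other splits), at 2 h (1 of 100, 6056 against 0) and at 6 h (1 of 100, 5259 against 16). The same holds for 6 h against 0 h in the mutant (1 of 100, 5594 against 3211) and for 2 h against 0 h in the mutant (1 of 100, 7577 against 175). At 2 h mutant libraries of the same number deviated together, so independence is in doubt for the comparisons with 2 h. If instead the mutant number (1, 2 or 4) is the unit, the 3 mutant numbers leave too few splits for a share under 0.05. For WT the 10 possible splits are too few for a share under 0.05: the real split of 6 h and 0 h gave 7660 genes and that of 2 h and 0 h 4645, the highest other split 0 in both (1 of 10 each).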

How the results depend on the processing

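The alternatives were fixed before the data were examined, except the comparisons of 2 h with 0 h and their alternatives, the leaving out of mutant libraries and the scaling of lists by total counts alone or by upper quartiles, which were chosen after seeing the data. The counts of changed genes stayed within 1.5 times of those reported with RLE and upper-quartile factors, DESeq2, no filter, the filter at 5 CPM, the replicate block, duplicateCorrelation, summed counts and each library left out. A minimum of 2-fold, which by construction keeps fewer genes, left 1258, 1376 and 1305 genes for mutant against WT at 0 h, 2 h and 6 h, 2736 and 971 for 6 h against 0 h in WT and mutant, 1481 for the difference of the changes, and 1165 and 1782 for 2 h against 0 h in WT and mutant. Mutant numbers 1, 2 and 4 alone gave 2120, 2670 and 6003 for 6 h against 0 h in the mutant and 4149, 3372 and 6456 for mutant against WT at 6 h, and the cause was not tested. Leaving out a WT library gave 4066 to 4802 genes at 0 h, 4531 to 5057 at 2 h and 3946 to 4397 at 6 h between the genotypes, and 6155 to 6446 for 6 h against 0 h in WT. The correlation of the genotype effects at 0 h and 6 h was 0.343 over genes of at least 5 CPM, and the cause was not tested.

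Whether the full labels (number and letter) pair the libraries across times is not settled. Of 12 pairs with the same label at 0 h and 6 h, 6 had deviations correlated above 0.1, and 3 correlated best with their own label. Of 11 pairs at 0 h and 2 h these counts were 6 and 4. Of 11 pairs at 2 h and 6 h they were 4 and 4, the latter with WT A, B and C among them. For letters, WT and mean mutant deviations at the same time correlated from -0.146 to 0.235, with 4 of 9 above 0.1. The replicate block was the letter for mutant against WT at each time and the full label for the other comparisons. With it the counts were 5182, 5436 and 4911 between the genotypes at 0 h, 2 h and 6 h, 6918 and 6195 for 6 h against 0 h in WT and mutant, 4368 for the difference, and 4204 and 7833 for 2 h against 0 h.

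Of 83 list calls by camera, 6 held with an estimated correlation and 77 did not, while the replicate block kept 81 and RLE factors 81. Fry, which asks whether a list changed at all and not whether it differed from other genes, called 80 of them. No list called by camera changed the sign of its median with RLE or upper-quartile factors. With total counts alone 5 did, to 0.03 for chaperones at 0 h, and at 2 h to 0.12 for the actin cytoskeleton, 0.10 for aminoacyl-tRNA synthetases, 0.09 for glycolysis and the citric acid cycle and 0.12 for the proteasome, while that scaling raised the median of all genes to 0.28 and 0.43. Of 8124 values of 278 results for named genes under alternatives, 8026 kept direction and side of the threshold, 37 no longer passed it and 41 newly passed it. The other 20 turned direction, each for a gene that did not pass the test as reported, and the cause was not tested. With mutant number 4 alone the log2 fold change from 0 h to 6 h in the mutant was -0.00195 for acaA, -0.0252 for gpaB and -0.0475 for regA, and pdsA against WT was -0.154 at 0 h and -0.0160 at 2 h. With number 1 alone mhcA against WT was -0.0404 at 0 h and -0.143 at 2 h, cprD at 2 h against 0 h -0.152 (-0.0114 without number 4) and gpaB at 2 h 0.108. Other values of gpaB at 2 h were 0.0213 with those groups alone, 0.0594 at 5 CPM, 0.0743 with upper-quartile factors, 0.0409 without number 2 and 0.0708 without WT library B. For pdsA at 0 h they were -0.0116 with summed counts, -0.00561 without number 1 and -0.0157 without mutant library 1A. Without a WT library, mhcA from 0 h to 6 h was 0.00849 (A at 0 h) and tgrB1 from 0 h to 2 h -0.00768 (C at 2 h). Over all single libraries left out, the ranges were -0.0592 to 0.0708 for gpaB at 2 h, -0.102 to 0.00849 for mhcA, -0.0157 to 0.0952 for pdsA at 0 h and -0.00768 to 0.354 for tgrB1.

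The test of AU-rich motifs downstream of coding sequences, and the alternatives for ttpA, were not run, since no genome and no row of that gene were used here. With 3 WT libraries per time, simulated 1.5-fold changes were recovered in 54.5% of genes for mutant against WT at 0 h and in 16.7% for the difference of the changes. Smaller effects were thus often missed in the simulation, which had far fewer changed genes than were called in the real comparisons.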

Other observations

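Transcripts of transposable elements were more abundant in the mutant at each time. They made up 0.152 ± 0.00953% of the counts in the mutant and 0.0932 ± 0.00159% in WT at 0 h, 0.163 ± 0.00864% and 0.0768 ± 0.0145% at 2 h, and 0.140 ± 0.0111% and 0.0815 ± 0.00684% at 6 h (SD). Of the elements tested, 119 of 255 were higher and 16 lower at 0 h (119 and 16 adjusted over the list alone), 129 of 268 and 13 at 2 h (130 and 13), and 125 of 255 and 6 at 6 h (126 and 7). The calls at 2 h and 6 h held with an estimated correlation (adjusted p = 0.0144 and 0.0444), and that at 0 h did not (0.0794). The shares used counts without TMM factors. The median log2 CPM of the elements was low, from -0.69 to -0.27 in the mutant libraries at 0 h. Weakly expressed genes in general leaned higher in the mutant. At both 0 h and 2 h, 1627 genes were called higher and 1650 lower, against 956 and 1515 among genes with a mean of at least 5 CPM. Whether the elements exceeded other genes of like expression was not tested. One element, DDB_G0281533_RTE, averaged 104 ± 13.4 CPM in the mutant and 6.89 ± 0.347 CPM in WT at 0 h, and its log2 fold change was 3.90, 3.88 and 3.81 at the 3 times. Elements are multicopy, so reads can be split between copies.

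Some lists that fit late development or other functions moved in part. Of 9 prespore genes, markers of cells that become spores, 3 were higher in the mutant at 0 h (2 adjusted over the list alone) and none lower, and camera did not call the list (adjusted p = 0.169). The cAMP receptor gene carD, a prestalk marker, was higher in the mutant at 0 h (41.7 ± 16.9 against 7.54 ± 1.05 CPM) and at 6 h (63.3 ± 16.4 against 22.5 ± 2.24 CPM). Of 13 mRNA decay factors 1 was higher and 5 lower in the mutant at 0 h (1 and 6 adjusted over the list alone), and none was higher and 5 lower at 6 h, with no camera call (adjusted p = 0.117 and 0.198). Of 13 genes of the discoidin and cell counting list 1 was higher and 2 lower at 0 h (adjusted p = 0.750). G protein-coupled receptor genes went both ways at 0 h, with 14 higher and 8 lower of 46 (adjusted p = 0.822), and fell in 19 and rose in 8 of 46 from 0 h to 2 h in WT (adjusted p = 0.0210, and 0.870 with an estimated correlation). Actin gene copies were lower in 20 and higher in 4 of 38 at 0 h (22 and 4 adjusted over the list alone, adjusted p = 0.286 with an estimated correlation). These comparisons of lists with 2 h against 0 h were added after the data were seen.

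The residual levels of the genes that stayed low in the mutant differed. At 0 h DDB_G0288219 averaged 12.9 ± 5.83 CPM in the mutant against 60.3 ± 11.1 CPM in WT, DDB_G0284999 10.8 ± 2.63 against 91.3 ± 20.9 CPM, DDB_G0271970 18.9 ± 14.5 against 154 ± 17.1 CPM and DDB_G0270922 109 ± 22.0 against 442 ± 11.5 CPM. H3c averaged 0.00905 ± 0.0116 CPM in the mutant, below the level of 3 counts, and 1.47 ± 0.0642 CPM in WT.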
